A study of Mus musculus with 12 samples.

How the data were processed

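Colorectal tumors had been induced in mice with azoxymethane, a carcinogen, and dextran sulfate sodium, which inflames the colon (AOM/DSS). The mice were wild type or carried a conditional deletion of Stat3 in myeloid cells. The labels do not name the driver of the deletion. Tumor and stroma were cut separately from paraffin-embedded tissue by laser-capture microdissection, and how the areas were chosen is not given in the sources used here. Each sample pooled 2 tumors of 1 mouse. RNA was extracted with a kit for fixed tissue, 50 ng were amplified and biotin-labelled with a kit for degraded RNA, and each sample was hybridised to 1 single-colour Affymetrix array, per the labels' protocols.

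The deposited values are log2 signals of 41345 probe sets that the authors computed by robust multi-array average (RMA) with Affymetrix Expression Console 1.3.1, per the submitters' processing notes. RMA subtracts background, forces the arrays onto 1 distribution at the probe level and summarises the probes of each probe set on the log2 scale. The log2 values were used as deposited. Array medians lay between 4.20 and 4.43 and the standard deviation (SD) of the values of an array between 1.60 and 1.91, so the deposited probe set values still differed in spread between arrays. The scanner files were not used here. The genome build and probe annotation behind the values are not given in the sources used here, so no genomic coordinates are given.

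Probe sets were named through the platform annotation supplied with the series. It listed 25335 probe sets, of which 23521 had 1 gene symbol and 1814 had several. Another 16010 probe sets were not listed and stay unnamed here. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which held 23328 of the named probe sets and changed 0 symbols. Of 22180 genes, 1082 had several probe sets, and the probe set with the highest mean over the 12 arrays stood for the gene. The 25% of genes with the lowest mean, below a log2 value of 3.65, were left out, which left 16635 genes.

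Each gene was fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 4 groups of 3 samples over all 12 arrays, and 5 contrasts were tested with moderated statistics (eBayes) and Benjamini-Hochberg adjustment within each contrast at 0.05. All adjusted p-values of single genes in the text are from this limma fit unless another is named. The contrasts were deletion minus wild type in stroma, the same in tumor, the difference between these (the interaction), and stroma minus tumor in each genotype. Gene lists written from general knowledge of the colon and its tumors numbered 38, with 581 distinct names. Matched directly or through synonyms, these gave 507 genes with a named probe set, of which 471 were tested. Some names were the old and new name of 1 gene, such as Emr1 and Adgre1. Through synonyms Loxl2 and Saa1 were matched to other genes, Loxl3 and Saa2. The 36 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, in both directions, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. An adjusted p of a list given without a named method is from the preset correlation. It is not comparable with values from an estimated correlation. Fry tests whether the genes of a list move on balance 1 way and does not compare the list with other genes. Members were also adjusted over their list alone. That adjustment leaves out the other genes and lists, and the lists shown were mostly those called on the same data. Counts of members passing over a list alone thus describe the list and are not calls of single genes. How often members pass this way without change was not simulated. The groups, the tests, the lists and the alternatives were fixed before the data were examined, except where another choice is named.

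The genes named in the text were chosen by a rule fixed at the same time. It takes Stat3. It takes the 12 largest rises and the 12 largest falls of a contrast among genes that passed and whose groups did not overlap (for the interaction without regard to overlap). Where fewer than 5 genes passed in a direction, it takes instead the 6 non-overlapping genes with the smallest unadjusted p in that direction. It adds the 4 members with the smallest p of each list that camera called and, between genotypes, the 2 members with the smallest p of the T cell, cytotoxic lymphocyte, macrophage, interferon-gamma, chemokine and STAT3 target lists. A fixed set of cell type markers completes it. Predicted genes, olfactory and vomeronasal receptors, small RNAs and gene segments of immune receptors were passed over among the genes taken by size or p. The text names a part of these. Other members named because they passed over a list alone, or with the replicate number as a block, were chosen after their values were seen.

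The labels number the samples 1 to 3 in each group but do not say what a number stands for. Whether equal numbers pair samples was checked from the correlation, over the tested genes, of each sample's deviations from its group mean, with pairing taken as given where all 3 correlations of a comparison exceeded 0.1. This held for wild type against deletion in tumor, with 0.317, 0.150 and 0.692 for the numbers 1, 2 and 3. It also held for tumor against stroma in the deletion, with 0.123, 0.157 and 0.298. The value of 0.692 joined the 2 arrays of widest spread. Unequal numbers also reached such values, with 0.125 for deletion tumor 1 and deletion stroma 2 and 0.330 for wild type tumor 2 and wild type stroma 1. A correlation above 0.1 thus did not separate equal from unequal numbers. Number 3 was also the widest array of each group. Its SD was 1.91 in wild type tumor, 1.76 in wild type stroma, 1.85 in deletion tumor and 1.72 in deletion stroma. Equal numbers and array spread are thus not separated. The pairing thus comes from the data, not from the labels, and same-numbered samples of different genotypes cannot be 1 mouse. For these comparisons the count of genes with the replicate number as a block stands beside the unblocked result.

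The test was tried on simulated data for deletion against wild type in stroma over 16635 genes. The arrays' own deviations from their group means, scaled up for the fitted means, were shuffled between arrays, given a random sign per array and added to the gene means, which keeps the correlation between genes. Of 200 genes changed in each of 20 simulations, 41.0% were called at a log2 change of 1, 94.9% at 2 and 99.5% at 3. The median of false calls was 0 and the mean 15.2. The changed genes were drawn at random, and the shares depend on their number, sizes and spread. In the measured stroma Reg3b, Car4 and Zg16 differed by 3.51, 3.16 and 2.75 log2 units between genotypes without passing. A count of 0 genes there thus does not mean that changes of this size were absent. In 50 simulations without change, 0 had a gene call, but camera with the preset correlation called a median of 12 lists and up to 24. With an estimated correlation 0 of the 50 simulations called a list, and with fry 4 did, with up to 4 lists in a simulation.

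Alternatives were quantile normalization, median centring, no filter and a filter at 50% on dim genes, the mean over probe sets, only the groups compared in the fit, a variance trend with robust moderation, array weights, the replicate number as a fixed or random block, and leaving out each sample. The SD of each array as a covariate, and leaving out the 2 arrays with the widest spread, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

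P-values treat the samples as independent. The labels say that a sample came from 1 mouse, but not that the 3 samples of a group came from different mice, nor whether tumor and stroma of a genotype came from the same mice. If samples share mice, p-values that ignore it can be too small or too large. For arrays there is no read depth, and their number limits the precision.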

Results

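Gene expression was measured on 12 arrays from laser-captured tumor and stroma of AOM/DSS-induced colorectal tumors, with 3 samples each of wild type tumor, wild type stroma, deletion tumor and deletion stroma, where deletion stands for mice lacking Stat3 in myeloid cells. STAT3 is a transcription factor activated by cytokines such as interleukin-6 and interleukin-10. The stated purpose was to find changes in the stroma that depend on STAT3 in myeloid cells. Arrays of 1 group correlated with each other at 0.881 to 0.967 over the 16635 genes tested, and 0 of the 66 pairs of arrays were identical over all probe sets. The widest arrays were wild type tumor 3, with an SD of its log2 values of 1.91, and deletion tumor 3, with 1.85. The narrowest was wild type stroma 1, with 1.60. The first principal component held 43.4% of the variance between arrays.

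**Figure D1:**
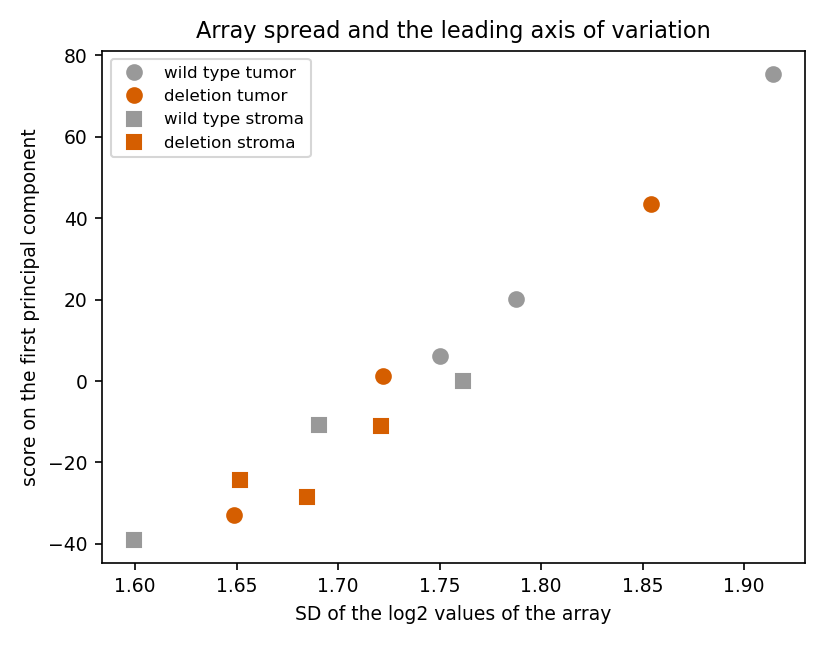
Score on the first principal component (vertical axis) against the SD of the log2 values of each array (horizontal axis) for the 12 arrays. Circles are tumor and squares stroma, in gray for wild type and orange for the deletion; wild type tumor 3 and deletion tumor 3 had SDs of 1.91 and 1.85.

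Stat3 itself was represented by 1 probe set. Its log2 level was 7.35 ± 0.65 (SD, n = 3) in wild type stroma and 7.36 ± 0.04 (SD, n = 3) in deletion stroma, a difference of 0.00 with a 95% confidence interval of -0.68 to 0.69. In tumor it was 7.71 ± 0.44 (SD, n = 3) in wild type and 7.44 ± 0.47 (SD, n = 3) in the deletion, a difference of -0.27 with an interval of -0.95 to 0.42. Neither difference passed the limma test (adjusted p = 0.999 in stroma and 0.858 in tumor). The deletion concerns myeloid cells only, and whether the probe set lies in the deleted part is not given, so Stat3 did not check the labels.

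The first comparison described what microdissection separated in wild type tumors. With the preset correlation camera called the list of epithelial cells lower in stroma than in tumor and those of fibroblasts, matrix and vessels higher, and none of these calls held with an estimated correlation (adjusted p = 0.436 to 0.494). All 18 tested members of the epithelial list lay below 0, with a median log2 difference of -1.06 (adjusted p of the list = 0.436 with an estimated correlation), and 15 passed when adjusted over the list alone. Among them, the adhesion molecules Epcam (log2 difference -0.90 ± 0.30 SE) and Cdh17 (-1.56 ± 0.35 SE) and the epithelial transcription factor Elf3 (-1.42 ± 0.30 SE) had adjusted p = 0.237, 0.185 and 0.185 over all genes.

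On the stromal side, 16 of 17 fibroblast genes lay above 0, with a median of 0.59 (adjusted p of the list = 0.494 with an estimated correlation), and Fbln2 (1.17 ± 0.31 SE) and Sfrp1 (1.81 ± 0.53 SE) passed over the list alone. Collagen and matrix genes had a median of 0.62, with 24 of 26 above 0 and 0 passing over the list alone (adjusted p of the list = 0.494 with an estimated correlation). Without wild type stroma 3 the medians of these 2 lists were 0.34 and 0.32. Endothelial genes had a median of 0.52 (0.29 without wild type stroma 3), and Eng, Vwf, Plvap and Lyve1 passed over the list alone (adjusted p of the list = 0.436 with an estimated correlation). T cell genes had a median of 0.54, with 11 of 12 above 0 and 1 passing over the list alone (adjusted p of the list = 0.436 with an estimated correlation). Goblet cell genes were lower, with all 10 below 0, a median of -1.20 and 7 passing over the list alone. Of these, the mucus proteins Zg16 and Fcgbp were 5.33-fold and 3.95-fold lower in stroma (adjusted p of the list = 0.436 with an estimated correlation). Among single genes, Klk1, a kallikrein protease, was 5.84-fold lower, Dmbt1, a scavenger protein of the mucosa, 4.05-fold lower, and Grem1, a secreted antagonist of bone morphogenetic proteins, 3.17-fold higher. The other 14 called lists were higher for smooth muscle, macrophages, dendritic cells, cytotoxic lymphocytes, B cells, mast cells, MHC class II, chemokines, matrix proteases and angiogenesis factors, with medians from 0.22 to 0.55 (adjusted p = 0.436 to 0.605 with an estimated correlation). They were lower for stem cell and Wnt targets (median -0.90), cell cycle (-0.33), hypoxia (-0.54) and ribosomal proteins (-0.40), with adjusted p = 0.501 to 0.684 with an estimated correlation. Of the members of each of these 14 lists 0 to 2 passed over the list alone. Without wild type stroma 3 the calls of smooth muscle, macrophages, B cells, mast cells, MHC class II, chemokines, matrix proteases, angiogenesis factors and cell cycle ended, with medians of 0.12, 0.03, 0.58, 0.04, 0.17, 0.02, 0.06, 0.22 and -0.25. Without wild type tumor 3 of cytotoxic lymphocytes ended, with 0.18. Leaving out wild type tumor 1, 2 or 3, wild type stroma 2, deletion tumor 1 or deletion stroma 1 ended 5, 4, 3, 1, 1 and 1 of these calls. Without wild type tumor 1 the medians of smooth muscle, mast cells, MHC class II and chemokines were 0.09, 0.26, 0.25 and 0.14. Without wild type stroma 1 those of smooth muscle, macrophages, cytotoxic lymphocytes and matrix proteases were 0.61, 0.73, 0.26 and 0.40. Those of smooth muscle, matrix proteases and angiogenesis factors were 0.22, 0.37 and 0.40 without wild type stroma 2, that of mast cells 0.16 without wild type tumor 2 and that of cell cycle -0.19 without wild type tumor 3.

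Other alternatives moved these lists too. With the array spread as a covariate the calls of stem cell and Wnt targets (-0.17), cytotoxic lymphocytes (-0.04), cell cycle (0.04) and ribosomal proteins (-0.20) ended. It gave medians of fibroblasts, collagens, smooth muscle, macrophages, mast cells, chemokines, matrix proteases and angiogenesis factors of 0.90, 1.07, 0.61, 0.76, 0.88, -0.0079, 0.07 and 0.37. Without the 2 arrays of widest spread the calls of cytotoxic lymphocytes (0.18), chemokines (0.16) and cell cycle (-0.19) ended. With array weights those of chemokines (0.11) and matrix proteases (0.10) ended. The medians of stem cell and Wnt targets, smooth muscle, cytotoxic lymphocytes, MHC class II, angiogenesis factors and hypoxia were then -0.41, 0.73, 0.26, 0.70, 0.15 and -0.84. The call of cell cycle ended after quantile normalization, which gave 0.36, -0.30 and -0.25 for matrix proteases, hypoxia and ribosomal proteins, and median centring gave 0.12, 0.12 and 0.14 for chemokines, matrix proteases and angiogenesis factors. Those of smooth muscle, chemokines and matrix proteases ended with no filter on dim genes, and that of matrix proteases with the mean over probe sets.

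In this comparison 0 of 16635 genes passed adjusted p 0.05 in limma, and the smallest adjusted p was 0.132. An unadjusted p under 0.05 was reached by 2783 genes, against 832 by chance. The 2 groups did not overlap for 23.9% of genes, against 10% by chance. Camera called 20 of 36 lists, 14 higher and 6 lower in stroma, 0 with an estimated correlation and 0 with fry. Without wild type stroma 2, 8 genes passed, with genotype and number together as a random block 5, and without wild type stroma 3, 11 lists were called.

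In deletion tumors camera with the preset correlation again called the epithelial list lower in stroma than in tumor, with the smallest p of all lists, and lists of leukocytes higher. None of these calls held with an estimated correlation (adjusted p = 0.0907 to 0.331). All 18 epithelial genes lay below 0, with a median of -0.92 (-0.53 without deletion stroma 2), 15 passing over the list alone and Epcam at -1.12 ± 0.30 SE (adjusted p of the list = 0.151 with an estimated correlation). Among single genes Cd53, a tetraspanin of leukocytes, was 4.03-fold higher in stroma (log2 2.01 ± 0.28 SE, adjusted p = 0.066). Ptprc, the common leukocyte antigen CD45, was 2.98-fold higher. The costimulatory molecule Cd86, the integrin chain Itgb2, the selectin ligand Selplg and the chemokine Ccl5 were 2.24-fold, 2.91-fold, 2.94-fold and 3.85-fold higher. All of these had non-overlapping groups of 3 and none passed in the main fit, which has no block. Macrophage and monocyte genes had a median log2 difference of 0.78, with 16 of 17 above 0 and 7 passing over the list alone, among them Ccr2 (1.15 ± 0.22 SE) and Cd68 (1.28 ± 0.36 SE; adjusted p of the list = 0.135 with an estimated correlation). T cell genes had a median of 0.63, with all 12 above 0 and 7 passing over the list alone (adjusted p of the list = 0.0907 with an estimated correlation). B cell genes had a median of 1.06, with 8 of 11 passing over the list alone, such as Cd79a (1.75 ± 0.42 SE, and 2.37 without deletion stroma 1). The B cell list had adjusted p = 0.117 with an estimated correlation. Cell cycle genes had a median of -0.58, with all 23 below 0 and 0 passing over the list alone (adjusted p of the list = 0.233 with an estimated correlation), and of -0.31 without deletion tumor 3. Mmp7, an epithelial protease, was 3.94-fold lower (log2 -1.98, with -1.30 as the mean over probe sets and -2.59 without deletion tumor 1). Other called lists were higher for MHC class II (median 0.81), chemokines (0.63), matrix proteases (0.63), immune checkpoints (0.62), fibroblasts (0.53), collagens (0.52), neutrophils (0.47), endothelium (0.46), smooth muscle (0.42), TGF-beta response (0.42), cytotoxic lymphocytes (0.34), NF-kB targets (0.32), the interleukin-10 list (0.31), dendritic cells (0.23), angiogenesis factors (0.20) and interferon-gamma targets (0.16), with adjusted p = 0.0907 to 0.445 with an estimated correlation. They were lower for stem cell and Wnt targets (-0.69), goblet cells (-0.58), histones (-0.57), hypoxia (-0.33) and ribosomal proteins (-0.32), with adjusted p = 0.117 to 0.586 with an estimated correlation. Of the members of each of these lists 0 to 7 passed over the list alone. Without deletion stroma 1 the calls of neutrophils, NF-kB targets, interferon-gamma targets and ribosomal proteins ended, with medians of -0.012, -0.0035, -0.00071 and -0.12. The medians of the interleukin-10 list, chemokines, matrix proteases, fibroblasts and hypoxia were then -0.04, 0.13, 0.37, 0.90 and -0.58. Without deletion stroma 2 the calls of goblet cells (-0.26) and hypoxia (-0.08) ended. The medians of fibroblasts, smooth muscle, dendritic cells, collagens, TGF-beta response and interferon-gamma targets were then 0.29, 0.26, 0.13, 0.32, 0.26 and 0.34. Without deletion stroma 3 the call of hypoxia (-0.40) ended, and the medians of neutrophils, dendritic cells, the interleukin-10 list, NF-kB targets and interferon-gamma targets were 0.81, 0.36, 0.58, 0.48 and 0.10. Without deletion tumor 3 the call of hypoxia (-0.11) ended, and the medians of stem cell and Wnt targets, cytotoxic lymphocytes, interferon-gamma targets and ribosomal proteins were -0.44, 0.21, 0.37 and -0.11. The call of interferon-gamma targets also ended without deletion tumor 2 (-0.07), and dendritic cells had a median of 0.40 without deletion tumor 1.

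Further alternatives moved the leukocyte and stromal lists of the deletion. With the array spread as a covariate the calls of neutrophils, cytotoxic lymphocytes, interferon-gamma targets and hypoxia ended. The medians of stem cell and Wnt targets, fibroblasts, the interleukin-10 list, chemokines, TGF-beta response, angiogenesis factors and ribosomal proteins were then -0.37, 0.82, 0.59, 0.39, 0.62, 0.31 and -0.17. With array weights the calls of neutrophils (0.28) and hypoxia (-0.29) ended. The medians of goblet cells, dendritic cells, cytotoxic lymphocytes, interferon-gamma targets, chemokines, angiogenesis factors, immune checkpoints and ribosomal proteins were then -0.38, 0.38, 0.21, 0.38, 0.37, 0.13, 0.40 and -0.20. Without the 2 arrays of widest spread the call of hypoxia (-0.11) ended, and the medians of stem cell and Wnt targets, cytotoxic lymphocytes, interferon-gamma targets, cell cycle and ribosomal proteins were -0.44, 0.21, 0.37, -0.31 and -0.11. After quantile normalization the call of hypoxia ended and the interferon-gamma median was 0.29.

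In limma 0 genes passed in the deletion, with 1610 at an unadjusted p under 0.05, against 832 by chance. The groups did not overlap for 13.7% of genes, against 10% by chance. With genotype and number together as a fixed block 152 genes passed, 109 higher and 43 lower in stroma, and with the same as a random block 62. The labels give no basis for either block. Number 3 was the widest array in both tissues of the deletion, so number and array spread are not separated here. Cd53, Cd86, Itgb2, Selplg, Ccl5, Ptprc, Ccr2, Ccr7 and Mmp7 passed with both blocks, and Cd68, Cd79a and Dcn with the first only (adjusted p = 0.0724, 0.0678 and 0.0722 with the random block). Camera called 26 lists, 19 higher and 7 lower, 0 with an estimated correlation and 3 with fry (T cells, immune checkpoints and histones). The count of genes was 33 after quantile normalization, 114 with the array spread as a covariate, 22 without wild type stroma 3, 13 without deletion stroma 1, 2 without deletion tumor 1 and 1 without wild type tumor 3.

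**Figure D2:**
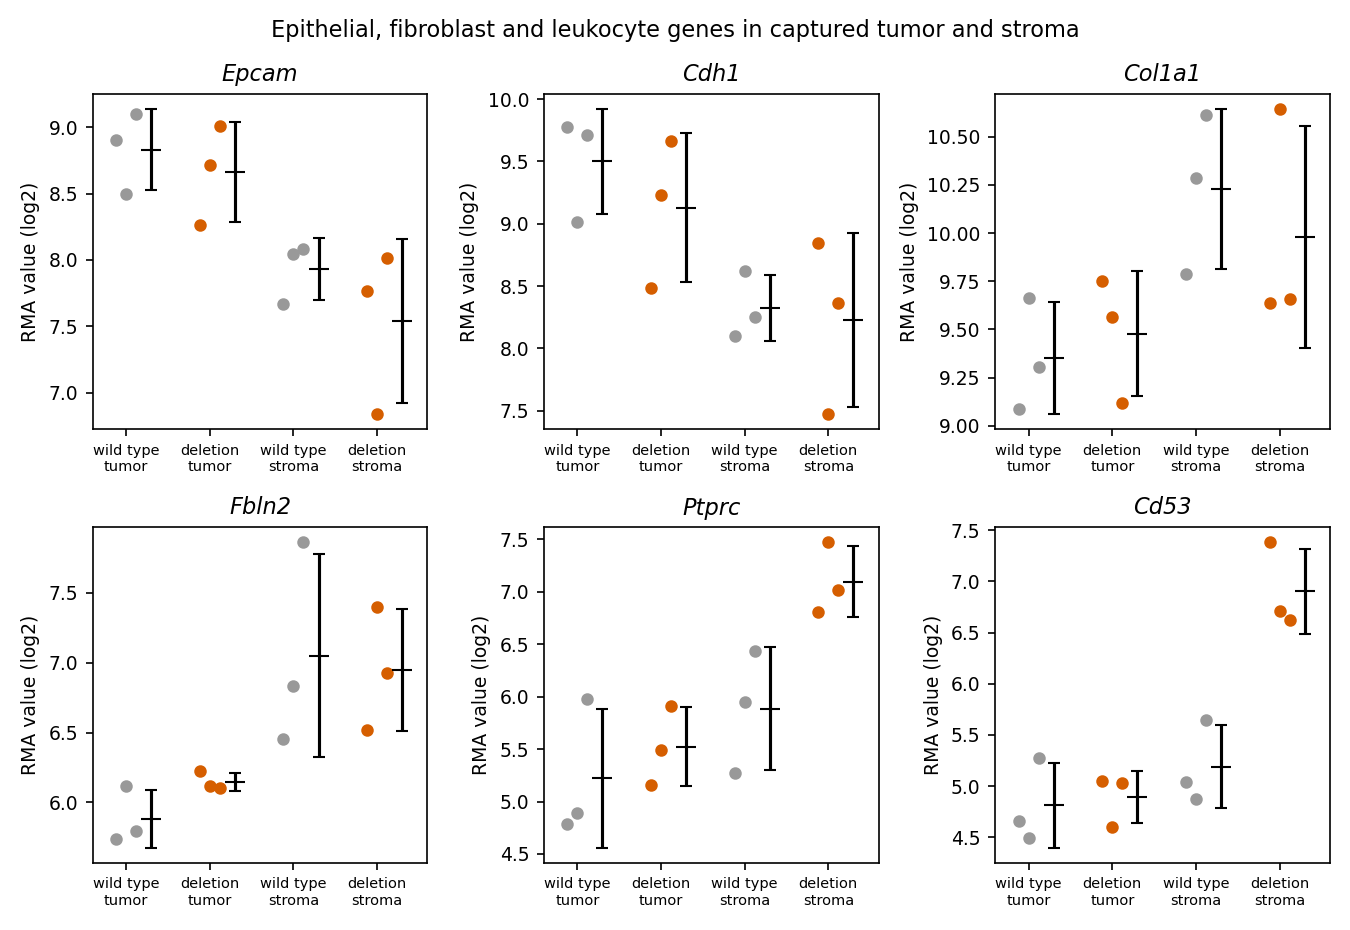
RMA log2 values (vertical axes, a separate range per gene) of the epithelial genes Epcam and Cdh1, the fibroblast genes Col1a1 and Fbln2 and the leukocyte genes Ptprc and Cd53 in the 4 groups of 3 samples (horizontal axes). Points are samples, in gray for wild type and orange for the deletion, and the bar beside them is the mean with its SD; Cd53 lay at 6.91 in deletion stroma and at 5.19 in wild type stroma.

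The comparison at the center of the study set deletion stroma against wild type stroma. No single gene passed. With the preset correlation camera called lists of the interferon-gamma response and of antigen presentation higher in deletion stroma and stem cell and Wnt targets lower, and these calls were lost with an estimated correlation (adjusted p = 0.0535 to 0.131). Of 20 interferon-gamma target genes, 19 lay above 0 with a median log2 difference of 0.72, and 10 passed when adjusted over the list alone (adjusted p of the list = 0.0535 with an estimated correlation). Cxcl9, a chemokine that attracts T cells, was 3.35-fold higher (log2 1.75 ± 0.36 SE), the guanylate-binding protein Gbp5 2.25-fold and the transcription factor Irf1 1.87-fold. All 10 genes of MHC class I presentation lay above 0 with a median of 0.65, and all 10 passed over the list alone (adjusted p of the list = 0.0535 with an estimated correlation), including H2-K1, a class I heavy chain (0.71 ± 0.20 SE), Tap2 of the peptide transporter (0.72 ± 0.18 SE) and the immunoproteasome subunit Psmb9 (0.84 ± 0.19 SE). MHC class II genes had a median of 0.97, with 10 of 10 above 0 and 8 passing over the list alone, such as H2-Ab1 at 1.22 ± 0.33 SE (adjusted p of the list = 0.0535 with an estimated correlation). Of these 3 lists fry called class I (adjusted p = 0.0181) and not the others (both 0.0573).

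Intestinal stem cell and Wnt target genes had a median log2 difference of -0.84 in deletion stroma, with 14 of 16 below 0 (adjusted p of the list = 0.131 with an estimated correlation). Axin2, Nkd1, Notum, Rnf43 and Tnfrsf19 passed over the list alone. Nkd1 and Notum, feedback inhibitors of Wnt signaling, were 5.18-fold and 4.42-fold lower. Colonocyte and goblet cell genes lay the other way (adjusted p = 0.110 and 0.0820 with an estimated correlation). Absorptive colonocyte genes had a median of 1.40 (0.63 without deletion stroma 1; adjusted p of the list = 0.110 with an estimated correlation), with 10 of 11 above 0 and 8 passing over the list alone, and the mean of this list was 7.81 in deletion stroma 1, the highest of all 12 arrays, against 6.27 and 5.61 in the others of its group. The ion transporter Slc26a3 was 4.25-fold and the carbonic anhydrase Car4 8.93-fold higher. Goblet cell genes had a median of 0.86 (0.56 without deletion stroma 1 and 1.35 without deletion stroma 2), with 9 of 10 above 0, and the lectin Zg16 was 6.73-fold higher (log2 2.75 ± 0.44 SE, adjusted p = 0.0956; adjusted p of the list = 0.0820 with an estimated correlation). The general epithelial list was not called (median 0.15, adjusted p = 0.377), and its mean was 8.20 in deletion stroma 1, 6.92 and 7.73 in the others of its group and 7.24 to 7.65 in wild type stroma.

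The T cell list was called higher beside these groups (adjusted p = 0.0820 with an estimated correlation), and the medians of the other leukocyte lists moved with single samples. Ptprc was 2.32-fold higher in deletion stroma (log2 1.21 ± 0.35 SE, adjusted p = 0.546), Cd53 3.28-fold and the T cell chemokine Ccl5 4.04-fold (both adjusted p = 0.0956). T cell genes had a median of 0.43, with all 12 above 0 and the costimulator Icos passing over the list alone (adjusted p of the list = 0.0820 with an estimated correlation). Macrophage and monocyte genes had a median of 0.34 (adjusted p of the list = 0.296 with an estimated correlation), with 15 of 17 above 0 and the monocyte genes Ly6c2 (1.63 ± 0.32 SE) and Ccr2 (0.73 ± 0.22 SE) passing over the list alone. Without wild type stroma 1 this median was -0.03 and the call ended, and without wild type stroma 3 it was 0.81. Neutrophil genes had a median of 0.59 (adjusted p of the list = 0.296 with an estimated correlation), with 13 of 13 above 0, although the median was -0.07 and the call ended without deletion stroma 1, and it was 0.24 without wild type stroma 3, 0.27 with no filter on dim genes and 0.26 with array weights. B cell genes had a median of 0.39, with Cd79a 3.75-fold higher (adjusted p of the list = 0.125 with an estimated correlation). The B cell median was 0.19 without deletion stroma 3, and 0.68, 0.61 and 0.70 without wild type stroma 2, wild type stroma 3 and deletion stroma 1. The mast cell list was called lower, with all 8 below 0, a median of -1.10 (-0.55 without wild type stroma 3 and -0.68 with array weights) and 4 passing over the list alone. The mast cell proteases Mcpt2 and Tpsb2 were 4.21-fold and 3.78-fold lower (adjusted p of the list = 0.110 with an estimated correlation).

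Lists of inflammatory genes lay above 0 as well, with values that leaned on deletion stroma 1 and adjusted p = 0.0622 to 0.279 with an estimated correlation. Cytokine and NF-kB target genes had a median of 0.55, with 19 of 21 above 0 and 0 passing over the list alone (adjusted p = 0.131 with an estimated correlation). Without deletion stroma 1 this median was 0.12 and the call ended (adjusted p = 0.299), and without deletion stroma 2 it was 0.83. The mean of these genes was 7.33 in deletion stroma 1, 5.73 and 5.75 in the others of its group and 5.79, 5.53 and 5.65 in wild type stroma. Deletion stroma 1 also had the highest mean of epithelial genes (8.20) and the lowest of fibroblast genes (6.49) among the 6 stroma samples. The T helper 17 and antimicrobial list had a median of 0.69, with 11 of 14 above 0 and 4 passing over the list alone, and a median of 0.19 without deletion stroma 1 and 0.41 without wild type stroma 3 (adjusted p of the list = 0.131 with an estimated correlation). Of the 4, the antimicrobial lectins Reg3b and Reg3g were 11.4-fold and 5.04-fold higher and the nitric oxide synthase Nos2 3.68-fold. Type I interferon targets had a median of 0.50 (0.31 without deletion stroma 1 and 0.30 with array weights) and only Irf7 passed over the list alone (adjusted p = 0.0622 with an estimated correlation). Chemokine genes had a median of 0.29, with 24 of 31 above 0 and Ccl5, Cxcl9 and Cxcl13 passing over the list alone, and cytotoxic lymphocyte genes 0.25, with Ccl5 passing (adjusted p = 0.118 and 0.279 with an estimated correlation). The call of the chemokines ended without deletion stroma 1 (0.15) and that of the cytotoxic lymphocytes without wild type stroma 3 (0.16), the chemokine median was 0.11 without wild type stroma 1 and 0.54 without wild type stroma 3, and the cytotoxic median was 0.15 with no filter.

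Other called lists were hypoxia (median 0.45), immediate early genes (0.31), immune checkpoints (0.27), dendritic cells (0.24), the interleukin-10 list (0.21), histones (-0.42), collagens (-0.30), endothelium (-0.17) and cell cycle (-0.12). With an estimated correlation the adjusted p of these lists = 0.0535 to 0.658, and 0 of their members passed over the list alone. The call of each, other than immune checkpoints, ended without at least 1 sample. Without deletion stroma 1 those of hypoxia (0.02), immediate early genes (0.23), the interleukin-10 list (0.10), histones (-0.22), collagens (-0.10), endothelium (0.0047) and cell cycle (-0.06) ended, and the median of immune checkpoints was 0.16. Without wild type stroma 1 those of dendritic cells (0.12), the interleukin-10 list (-0.02), histones (-0.16) and cell cycle (-0.02) ended. The calls of the interleukin-10 list (0.11) and cell cycle (-0.11) ended without wild type stroma 2, those of collagens (0.04) and endothelium (-0.0058) without wild type stroma 3, and those of dendritic cells (0.0095), histones (-0.42) and cell cycle (-0.06) without deletion stroma 2. The remaining medians that moved by over 1.5 times were collagens (-0.49) and endothelium (-0.33) without wild type stroma 1, endothelium (-0.27) without wild type stroma 2, and the interleukin-10 list (0.37), hypoxia (0.30) and cell cycle (-0.22) without wild type stroma 3. Others were collagens (-0.49), endothelium (-0.27) and hypoxia (0.68) without deletion stroma 2, immune checkpoints (0.42), collagens (-0.12) and cell cycle (-0.30) without deletion stroma 3, and dendritic cells (0.37) without deletion tumor 3. The call of the interleukin-10 list also ended after quantile normalization, those of the interleukin-10 list and dendritic cells with the mean over probe sets, that of histones with no filter, and those of endothelium (-0.09), dendritic cells (0.20), cell cycle (-0.07) and histones (-0.25) with array weights. Array weights gave medians of 0.32, -0.16 and 0.20 for the interleukin-10 list, collagens and immediate early genes, and the dendritic cell median was 0.37 with no filter or without the 2 arrays of widest spread. The STAT3 target list was not called, with 13 of 21 genes above 0 and a median of 0.20 (adjusted p = 0.0914 with the preset correlation). Nor were fibroblast genes (median -0.10) and smooth muscle genes (median -0.10), with adjusted p = 0.452 and 0.527. The single gene with the smallest p was Dkk2, a secreted modulator of Wnt signaling, at 5.79 ± 0.41 (SD, n = 3) in wild type and 3.98 ± 0.35 (SD, n = 3) in deletion stroma. It was 3.49-fold lower with adjusted p = 0.0637 in limma. The keratin Krt36, the laminin chain Lama5 and the Wnt target Apcdd1 were 4.23-fold, 2.32-fold and 4.38-fold lower.

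In stroma 0 of 16635 genes passed in limma, with 844 at an unadjusted p under 0.05 against 832 by chance, and the groups did not overlap for 10.8% of genes, against 10% by chance. Camera called 25 lists, 19 higher and 6 lower, 0 with an estimated correlation and 1 with fry, and 0 of 50 simulations without change reached 25, although they called a median of 12. Without any 1 sample, 5 of the 25 lists (interferon-gamma targets, MHC class I, MHC class II, T cells, and stem cell and Wnt targets) stayed called with medians within 1.5 times, and 20 did not. The count of lists was 16 without deletion stroma 1, and the count of genes 13 with the array spread as a covariate, 2 without wild type stroma 2 and 1 without wild type stroma 1 or any 1 of the 3 deletion stroma samples.

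**Figure D3:**
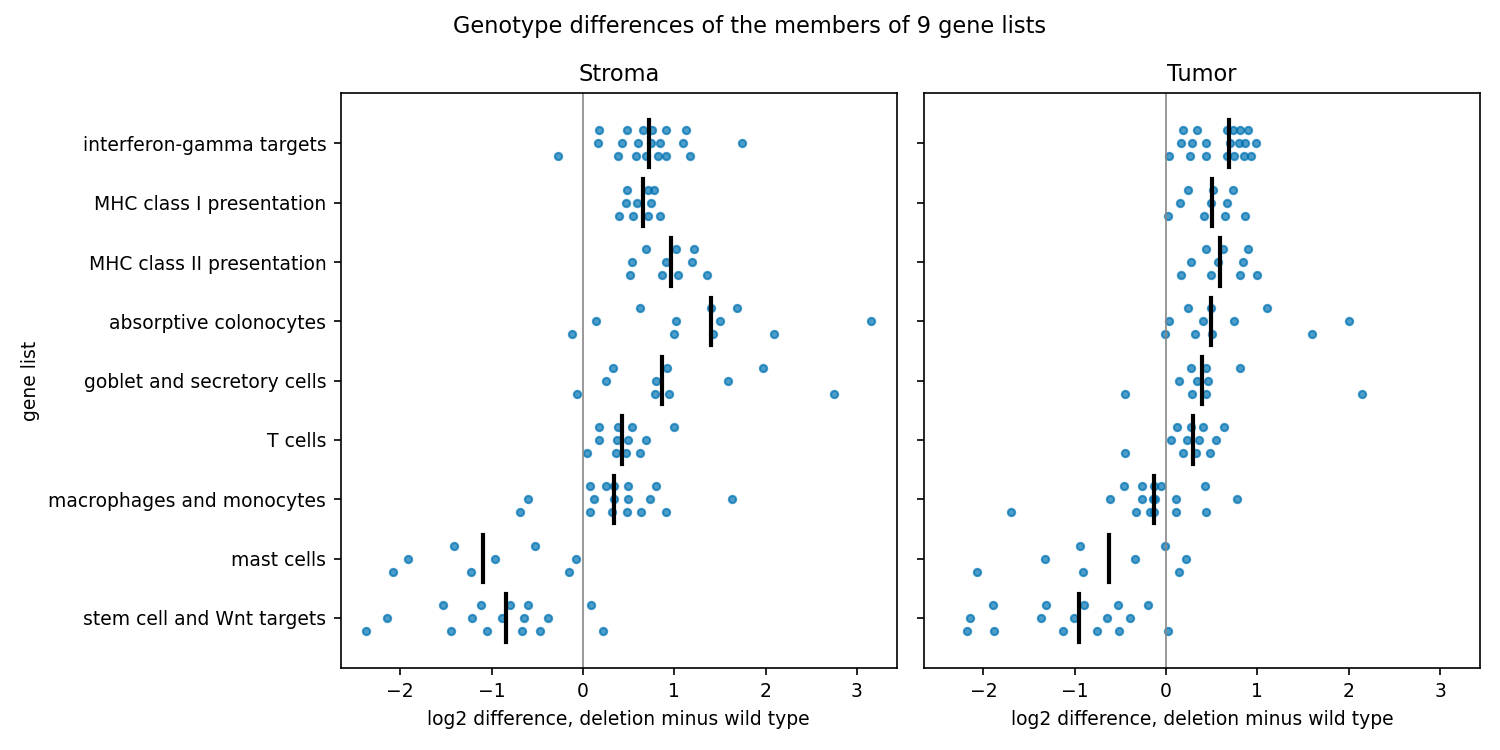
Log2 differences between deletion and wild type (horizontal axes) of the members of 9 gene lists (vertical axis) in stroma and in tumor. Each point is a gene and each black line the median of its list, such as 0.72 in stroma and 0.69 in tumor for interferon-gamma targets and -0.84 and -0.95 for stem cell and Wnt targets; the vertical offset of points has no meaning.

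In captured tumor tissue, 3 genes fell in the deletion. Dkk2 was 4.46-fold lower (log2 -2.16 ± 0.25 SE, adjusted p = 0.0076), at 6.89 ± 0.18 (SD, n = 3) in wild type and 4.74 ± 0.28 (SD, n = 3) in the deletion. Stra6, the cell surface receptor for retinol-binding protein, was 7.09-fold lower (-2.83 ± 0.37 SE, adjusted p = 0.0136). Plat, tissue plasminogen activator, was 4.89-fold lower (-2.29 ± 0.34 SE, adjusted p = 0.0466). Apcdd1 was 7.97-fold lower, the mucin Muc6 3.19-fold and the teneurin Tenm4 4.03-fold, with adjusted p = 0.0531, 0.0531 and 0.0563. Apcdd1 had a log2 difference of -3.00, and -2.37 without deletion tumor 1, and Muc6 one of -1.68, and -1.05 with array weights. With the replicate number as a block across genotypes 89 genes passed, 9 higher and 80 lower, and they included Dkk2, Stra6, Plat, Apcdd1, Muc6 and Tenm4. This block has no basis in the labels. It also spans the stroma arrays, whose equal numbers correlated at 0.152, -0.040 and 0.113 between genotypes. In tumor, number 3 holds the 2 arrays of widest spread, so number and array spread are not separated there. With genotype and number together as a random block 3 genes passed, Dkk2, Stra6 and Apcdd1 (adjusted p = 0.00806, 0.0190 and 0.0419), while Plat, Muc6 and Tenm4 did not (0.0557, 0.0610 and 0.0610).

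On the higher side none passed in the main fit or with the random block. With the number as a block the antimicrobial lectins Reg3b and Reg3g (both adjusted p = 0.00194 with the block), the inflammasome sensor Nlrp6, the neuropeptide precursor Tac1, the water channel Aqp4 and Ccl5 passed. Reg3b was 33.5-fold higher, at 11.79 ± 0.41 (SD, n = 3) in deletion tumor and 6.73 ± 2.87 (SD, n = 3) in wild type tumor, where sample 1 stood at 10.04 and the others at 4.91 and 5.23. Its log2 difference was 5.07, with 6.72, 4.16 and 4.32 without wild type tumor 1, 2 and 3, 4.44 with the array spread as a covariate or without the 2 arrays of widest spread and 2.22 with array weights. That of Reg3g was 3.51, with 4.43 without wild type tumor 1, 2.89 with the covariate and 1.75 with array weights. Without the block Reg3b had adjusted p = 0.154, with the random block 0.113, and 0.00458 without wild type tumor 1, in a range of 0.00194 to 0.784 over 24 alternatives. For Reg3g the adjusted p was 0.187 in the main fit, 0.121 with the random block, 0.0446 without wild type tumor 1 and 0.0382 with array weights.

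With the preset correlation camera called interferon-gamma targets and genes of MHC class I and II higher and Wnt targets lower in deletion tumor too, and with an estimated correlation it called none of them (adjusted p = 0.419 to 0.456). Interferon-gamma targets had a median of 0.69, with all 20 above 0 and 7 passing over the list alone, such as the immunity-related GTPase Iigp1 (0.99 ± 0.30 SE; adjusted p of the list = 0.419 with an estimated correlation). MHC class I genes had a median of 0.50 with 10 of 10 above 0 and 6 passing over the list alone, and class II genes 0.60 with 10 of 10 above 0 and 2 passing over the list alone. Adjusted p was 0.419 for the class I list and 0.443 for the class II list with an estimated correlation. Without the 2 arrays of widest spread the interferon-gamma and class I medians were 0.42 and 0.29, and with array weights 0.23 and 0.25. Stem cell and Wnt target genes had a median of -0.95 (-0.63 without deletion tumor 1), with 15 of 16 below 0 and 9 passing over the list alone (adjusted p of the list = 0.456 with an estimated correlation). Of these, Axin2, Lef1, Prox1 and Wif1 were 2.59-fold, 2.49-fold, 4.55-fold and 4.41-fold lower, and each passed with the replicate number as a block but not with the random block (adjusted p = 0.399, 0.251, 0.379 and 0.325). Prox1 and Wif1 had log2 differences of -2.18 and -2.14, with -1.32 and -1.28 without deletion tumor 1, -1.42 and -1.52 with the array spread as a covariate and -1.49 and -1.41 with array weights. The T helper 17 and antimicrobial list had a median of 0.35, with Reg3b and Reg3g as the members that passed over the list alone (adjusted p of the list = 0.477 with an estimated correlation). Absorptive colonocyte genes had a median of 0.49, with Car4 and Slc26a3 (3.03-fold higher) passing over the list alone, and goblet cell genes 0.39 (both adjusted p = 0.501 with an estimated correlation). T cell genes had a median of 0.30, cytotoxic lymphocyte genes 0.28, TGF-beta response genes -0.36 and matrix proteases -0.37. These 6 lists were called, each with adjusted p = 0.501 with an estimated correlation and 0 to 2 members passing over the list alone. The calls of colonocytes (0.15), goblet cells (0.36) and matrix proteases (-0.45) ended without wild type tumor 2, those of goblet cells (0.22) and matrix proteases (-0.38) without deletion tumor 3, that of goblet cells (0.30) without wild type tumor 1 and that of cytotoxic lymphocytes (0.13) without wild type tumor 3. The T cell median was 0.18 without wild type tumor 3 and the cytotoxic median 0.43 without wild type tumor 2. With the array spread as a covariate the call of cytotoxic lymphocytes ended and the TGF-beta median was -0.14, without the 2 arrays of widest spread the calls of T cells, TGF-beta response and matrix proteases ended and the goblet and cytotoxic medians were 0.22 and 0.17. With array weights the calls of goblet cells (0.24), colonocytes (0.12), cytotoxic lymphocytes (0.20), TGF-beta response (-0.13), matrix proteases (-0.15) and the T helper 17 list (0.11) ended, and after quantile normalization that of matrix proteases (-0.25). Of lists called in stroma, macrophages (median -0.13), NF-kB targets (-0.17), immediate early genes (-0.08), the interleukin-10 list (-0.10), cell cycle (0.10) and histones (0.16) had medians of the opposite sign in tumor and were not called there (adjusted p = 0.147 to 0.853). Not called either were mast cell genes (median -0.62, adjusted p = 0.0836 with the preset correlation). The STAT3 target list was not called (adjusted p = 0.863). Its median was -0.09 and its mean 0.03, and Lrg1, an acute-phase glycoprotein, was 3.90-fold higher and passed over the list alone.

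The 3 genes that passed in limma compared with 1042 at an unadjusted p under 0.05, against 832 by chance. The groups did not overlap for 9.5% of genes, against 10% by chance. Camera called 11 lists, 8 higher and 3 lower, 0 with an estimated correlation and 0 with fry. Of the 3 genes 0 passed without wild type tumor 3, an array of wide spread, when Dkk2 had adjusted p = 0.0603, Stra6 0.0626 and Plat 0.206. Over the 24 alternatives Dkk2 passed in 22, Stra6 in 20 and Plat in 10, with the highest adjusted p at 0.0725, 0.14 and 0.206. The count was 1 without wild type tumor 2, 2 without wild type stroma 3, deletion tumor 1, deletion tumor 2 or deletion stroma 3, 5 without wild type stroma 2 or deletion tumor 3, 7 without wild type tumor 1 or wild type stroma 1, and 14 with the array spread as a covariate.

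**Figure D4:**
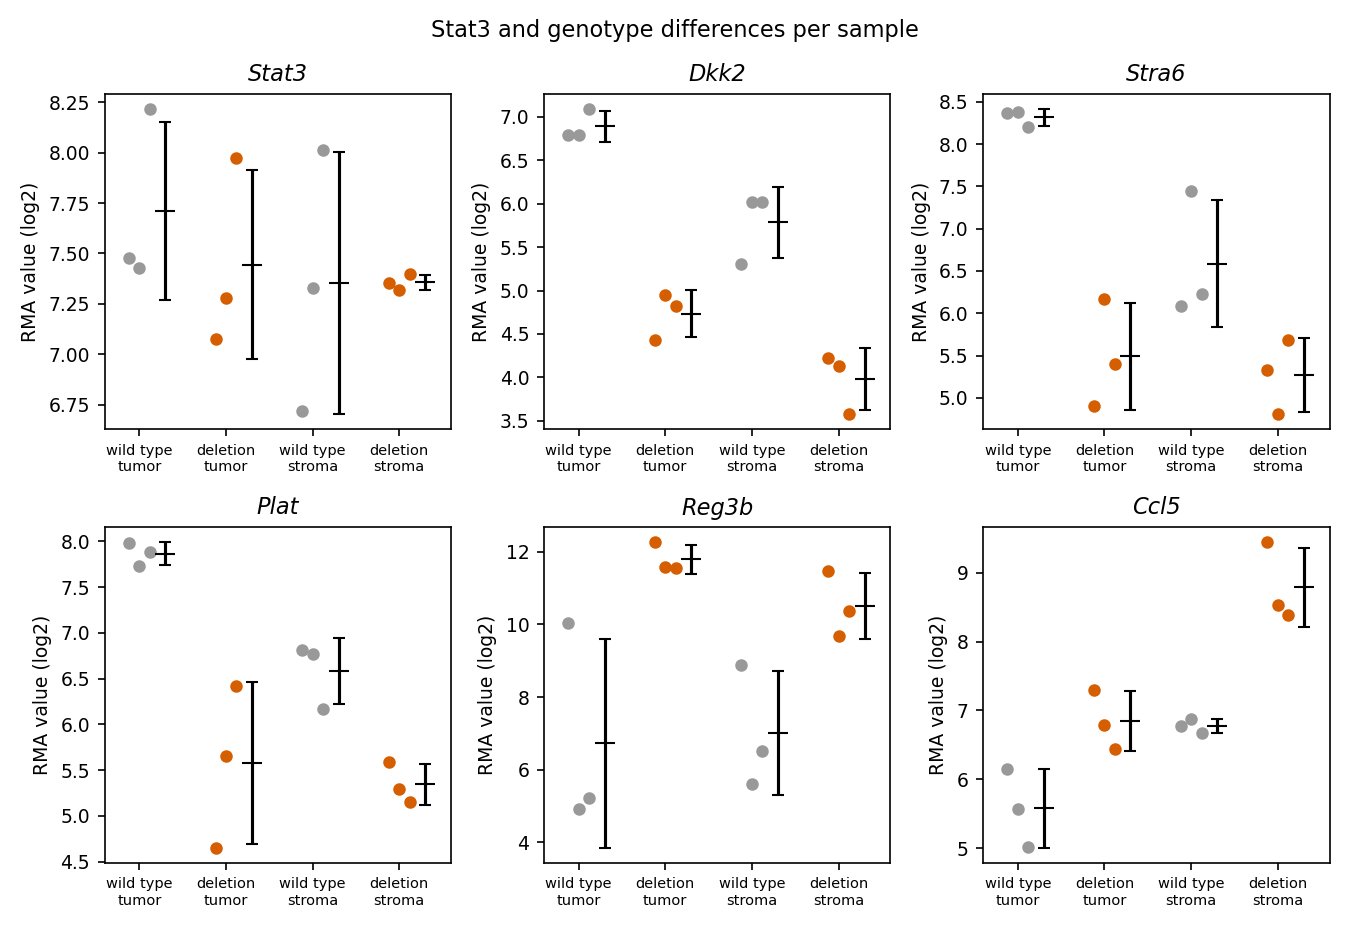
RMA log2 values (vertical axes, a separate range per gene) of Stat3, of Dkk2, Stra6 and Plat, which passed the test in tumor, and of Reg3b and Ccl5 in the 4 groups of 3 samples (horizontal axes). Points are samples, in gray for wild type and orange for the deletion, and the bar beside them is the mean with its SD; Dkk2 lay at 6.89 and 4.74 in wild type and deletion tumor, and Stat3 overlapped between genotypes in both tissues.

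Whether the genotype difference itself differed between stroma and tumor was tested as an interaction. No single gene passed. The largest evidence was for Cd86, Phf11b and Cd53, whose difference was 1.23 ± 0.26 SE, 1.27 ± 0.28 SE and 1.63 ± 0.40 SE log2 units higher in stroma than in tumor, all with adjusted p = 0.995. Cytokine and NF-kB target genes had a median of 0.61 in this contrast, with 18 of 21 above 0, macrophage and monocyte genes 0.56, immediate early genes 0.44, type I interferon targets 0.43 and cell cycle genes -0.27. These 5 lists were called, each with adjusted p = 0.785 with an estimated correlation and 0 members passing over the list alone. The call of each ended without at least 1 sample. For NF-kB targets this was deletion stroma 1 (median 0.20). For macrophages it was wild type tumor 2 (0.52) or wild type stroma 1 (0.09), with 0.86 without wild type stroma 3 and 0.35 without deletion tumor 1. For immediate early genes it was wild type tumor 1 (0.29) or deletion stroma 1 (0.35), and for type I interferon targets wild type tumor 1 (0.33), wild type tumor 2 (0.44), wild type stroma 3 (0.38) or deletion stroma 1 (0.46). For cell cycle genes it was wild type tumor 2 (-0.13), wild type stroma 1 (-0.17), deletion tumor 3 (-0.03) or deletion stroma 2 (-0.11), with -0.46 without deletion tumor 1 and -0.42 without deletion stroma 3. The macrophage call also ended with array weights or the array spread as a covariate, and the cell cycle call without the 2 arrays of widest spread, where the immediate early median was 0.71. The cell cycle median was -0.42 with the covariate and -0.41 after quantile normalization, which gave 0.25 for immediate early genes. The interferon-gamma list (median 0.05, adjusted p = 0.547) and the Wnt list (median 0.06, adjusted p = 0.761) were not called, both with the preset correlation. In limma 0 genes passed and 401 had an unadjusted p under 0.05, fewer than the 832 by chance. The count of lists was 0 with an estimated correlation or fry, 3 and 2 without wild type tumor 1 and 2, 14 without wild type tumor 3, 10 without wild type stroma 1 or 3, 8 without deletion tumor 1, and 13 and 12 without deletion stroma 2 and 3.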

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

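The splits of the arrays for counts of genes were chosen after those counts were seen, those for counts of lists before. The lists below were picked out because the test of the difference between tissues called them with the preset correlation. None was called with an estimated correlation (each adjusted p = 0.785) or by fry (each 0.851). The median log2 values of this interaction were 0.56 for macrophages and monocytes, 0.61 for inflammatory cytokines and NF-kB targets, 0.43 for type I interferon targets, 0.44 for immediate early genes and -0.27 for cell cycle and proliferation. The call of each ended without at least 1 sample. The median was then 0.09 for macrophages without wild type stroma 1, 0.20 for NF-kB targets without deletion stroma 1, 0.33 for type I interferon targets and 0.29 for immediate early genes without wild type tumor 1, and -0.03 for cell cycle without deletion tumor 3, and other samples also ended calls (wild type tumor 2, wild type stroma 3 and deletion stroma 2). Of 100 drawn assignments of genotype to the arrays within each tissue, the real one included, 91 called as many lists as the 5 observed, and the highest other called 28, so chance was not excluded for this count. For single genes the count was 0 in the real split and in all 100, with 0 as the highest other. The 13368 probe sets that had no single gene name and passed the same filter gave 0 calls in each of the 5 contrasts, with 631 in stroma and 479 in tumor at an unadjusted p under 0.05 between genotypes in limma.

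The other counts come from 3 arrays against 3, whose 10 splits are too few for a share under 0.05. For genes between genotypes the real split gave 0 in stroma, reached by all 10 splits with 0 as the highest other, and 3 in tumor, reached by 1 split with 0 as the highest other. Between stroma and tumor it gave 0 genes in each genotype, reached by all 10 splits, with 0 as the highest other. For lists the real split gave 25 in stroma with 22 as the highest other, 11 in tumor with 17, 20 between stroma and tumor in wild type with 20, and 26 in the deletion with 21; these counts were reached by 1, 3, 2 and 1 of the 10 splits. Among the 4 splits that part all 3 number pairs in tumor, the fit with the replicate number as a block gave 89 genes in the real split and 0 in the others. Between stroma and tumor in the deletion, with genotype and number as the block, it was 152 and 0. These splits are too few for a share under 0.05. The pairing was also judged from deviations from the real group means, so the blocked counts do not exclude chance. Without the block the highest other of these 4 called 14 lists in tumor, and 17 came from a split that parts fewer pairs; in the deletion both kinds reached 21.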

How the results depend on the processing

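The array spread as a covariate and leaving out the 2 widest arrays were chosen after seeing the data. Counts of genes are given in the order genotype in stroma, genotype in tumor, interaction, stroma against tumor in wild type, and stroma against tumor in the deletion, where the main counts were 0, 3, 0, 0 and 0. No filter, the mean over probe sets and only the groups compared (not run for the interaction) gave the same counts, although with only the groups compared 1 of the 3 genes in tumor was higher and 2 lower. Quantile normalization gave 1, 3, 0, 0 and 33, median centring 0, 2, 0, 0 and 0, the filter at 50% and the variance trend each 5 in tumor and 0 elsewhere, and leaving out the 2 widest arrays 2 in tumor and 0 elsewhere. The array spread as a covariate gave 13, 14, 0, 0 and 114. Array weights gave 164, 1579, 4, 3963 and 727, with array weights from 0.258 to 7.80 and a warning of incomplete convergence. The replicate number as a fixed block gave 28, 89, 0, 138 and 152. That block was the number alone for the genotype differences and genotype and number together for the others. Genotype and number together as a random block gave 0, 3, 0, 5 and 62. The numbers did not pair the samples for genotype in stroma, stroma against tumor in wild type, and the interaction. There the pairs correlated from -0.04 to 0.152 between genotypes in stroma and from -0.00 to 0.512 in wild type. Over both genotypes 9 of the 12 samples correlated best with the own number in the other tissue. This comes from the data and not from the design. Number 3 was the widest array of each group, so shared mice and array spread cannot be told apart here. Leaving out 1 sample gave 0 to 2, 0 to 7, 0 to 0, 0 to 8 and 0 to 22 genes.

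Counts of lists, in the same order, were 25, 11, 5, 20 and 26. With an estimated correlation they were 0 throughout, and with fry 1, 0, 0, 0 and 3. The interaction called 10 lists with no filter, 16 with array weights, 9 with the replicate number as a block, 12 with the spread covariate and 10 without the 2 widest arrays, and the genotype difference in tumor 7 with array weights. The block changed no other count of lists by over 1.5 times. Leaving out 1 sample gave 16 to 27, 9 to 15, 2 to 14, 11 to 24 and 24 to 28 lists. The Stat3 difference in stroma, 0.00, was -0.012 after quantile normalization, -0.0044 with array weights, -0.0068 with the spread covariate, and -0.32 to 0.33 without 1 sample. In tumor, -0.27, it was 0.14 with the spread covariate and -0.53 to -0.01 without 1 sample. The Stat3 interaction, 0.27, was -0.15 with the spread covariate and -0.0492 to 0.601 without 1 sample, lowest without wild type stroma 1. None of these Stat3 values passed. Camera's direction turned for cell cycle in wild type stroma against tumor (median 0.044 with the spread covariate), and, over left-out samples, for collagens between genotypes in stroma (-0.49 to 0.042, highest without wild type stroma 3), neutrophils there (-0.073 to 0.83, lowest without deletion stroma 1), NF-kB targets in deletion stroma against tumor (-0.00352 to 0.483, lowest without deletion stroma 1) and hypoxia there without deletion stroma 2, although its median stayed below 0 (-0.58 to -0.080). Other medians changed sign while camera's direction stayed, between genotypes in stroma for macrophages and the interleukin-10 list (-0.03 and -0.02 without wild type stroma 1) and endothelium (0.0047 without deletion stroma 1), and in wild type stroma against tumor for cytotoxic lymphocytes and chemokines (-0.04 and -0.0079 with the spread covariate). In deletion stroma against tumor they did so for neutrophils, the interleukin-10 list and interferon-gamma targets (-0.012, -0.04 and -0.00071 without deletion stroma 1) and for the last without deletion tumor 2 (-0.07). Without 1 sample the call ended or the median moved by over 1.5 times for 20 of 25, 6 of 11, 5 of 5, 13 of 20 and 18 of 26 lists. The cause was not tested for any of these changes, except that a left-out sample leaves fewer samples and a filter tests fewer genes. Lists were not run with the filter at 50%, only the groups compared, the variance trend or the random block. How far signals stood above background was not tested here. Of the values of named genes between genotypes in tumor, 757 of 839 kept their direction and side of the threshold, and in stroma 963 of 1022. Between stroma and tumor 646 of 696 did so in wild type and 521 of 620 in the deletion. In the interaction 244 of 249 did, and 2 reversed. As few or no genes passed in the main fit, keeping the side mostly meant staying uncalled.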

Other observations

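Tests chosen after the result was seen in this part are those of array spread, of leukocytes in the captured stroma and of the groups on the leading axis. Averaging the genotype difference over tumor and stroma was a contrast added after seeing the data. It gave 47 genes in limma at adjusted p 0.05, 14 higher and 33 lower in the deletion. An unadjusted p under 0.05 was reached by 1369 genes, against 832 by chance. Dkk2 fell most clearly, by 1.98 on the log2 scale (SE 0.18, adjusted p = 0.000279), and Stra6 fell by 2.07, with Apcdd1, Plat, Muc6, Tenm4 and Krt36 5.91-fold, 3.40-fold, 2.74-fold, 3.05-fold and 4.12-fold lower. Among the other genes that fell were the axon guidance receptor Robo1 (3.51-fold), the tight junction protein Cldn4 (2.80-fold), the keratin Krt23 (4.45-fold), the transcription factor Tbx3 (2.44-fold), the growth factor Bmp7 (2.09-fold) and the mast cell protease Mcpt1 (3.34-fold). Genes that rose included Reg3b (19.5-fold, log2 4.29, and 5.11 without wild type tumor 1), Reg3g (7.58-fold), the colonocyte genes Car4 (5.97-fold) and Slc26a3 (3.59-fold), Aqp4 (4.35-fold), Dmbt1 (2.86-fold), the vitamin D receptor Vdr (2.11-fold), Nlrp6 (2.39-fold), Ccl5 (3.11-fold), Cxcl9 (2.53-fold), Psmb9 (1.73-fold) and the monocyte gene Ly6c2 (2.31-fold). The genes of this contrast were named after their values were seen. Of the lists, MHC class I, MHC class II and interferon-gamma targets were called by fry (adjusted p = 0.00453, 0.0446 and 0.0199), each with adjusted p = 0.0685 with an estimated correlation. Fry took the 12 arrays as independent here, and the interferon-gamma list shares members with the other 2. In the stroma simulations without change, fry called up to 4 lists at once, so chance was not excluded for these calls.

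When genotype was reassigned within each tissue, 1 of 100 drawn splits, the real one, gave as many as 47 genes. The highest other gave 1. This share counts against chance only if tumor and stroma samples are independent, and the contrast was added after seeing the data. The samples are not independent if equal numbers within a genotype are 1 mouse. By correlation, 9 of the 12 samples lay closest to the own number in the other tissue, so chance was not excluded for this count. Keeping equal numbers together leaves 10 splits, too few for a share under 0.05, with 6 genes as the highest other. A fit on the mean of tumor and stroma per genotype and number called 6 genes (Dkk2, Stra6, Muc6, Plat, Car4 and Dmbt1). One with genotype and number together as a random block called 13. The count was 92 after quantile normalization, 17 after median centring, 166 with the array spread as a covariate, which kept all 47, and 16 to 69 without 1 sample, lowest without deletion stroma 3. Across genes, which are not independent replicates, the genotype differences in stroma and tumor correlated at 0.354. As high a value came from 8 of 100 splits and the highest other was 0.452 (0.571 with equal numbers kept together), so chance was not excluded for the correlation as a whole.

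Interferon-gamma targets had a median log2 difference of 0.72 in deletion stroma, a list called with the preset correlation but neither with an estimated correlation (adjusted p = 0.0535) nor by fry (0.0573). Array spread was not tested by using it as a covariate (median again 0.72), because its mean was nearly equal in wild type and deletion stroma (1.68 and 1.69), so that the covariate could not move the difference. More leukocytes in the captured stroma may contribute and stays open, since 5 lists of leukocyte markers had medians from 0.24 to 0.59 (adjusted p = 0.0820 to 0.296 with an estimated correlation), and many interferon-gamma targets are expressed by leukocytes. Of these lists neutrophils had the highest median, 0.59, but -0.07 without deletion stroma 1 and 0.26 with array weights, macrophages had -0.03 without wild type stroma 1, B cells 0.19 without deletion stroma 3 and dendritic cells 0.0095 without deletion stroma 2, while mast cell genes, also of leukocytes, had -1.10 (-0.55 without wild type stroma 3, -0.68 with array weights, adjusted p = 0.110 with an estimated correlation). A response to interferon-gamma that depends on Stat3 in myeloid cells stays open too and was not tested separately.

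Wnt target genes had medians of -0.84 in stroma and -0.95 in tumor of the deletion, called in both with the preset correlation and in neither with an estimated correlation (adjusted p = 0.131 and 0.456) or by fry (0.173 and 0.479). In tumor, where the median was -0.63 without deletion tumor 1, it was -0.66 with the array spread as a covariate, which argues against spread as the whole cause there, while in stroma the covariate (-0.86) could not move the difference and tested nothing. Non-tumor epithelium in the captured areas could lower Wnt targets and raise colonocyte genes, whose mean was highest in deletion stroma 1 (7.81). After removing group means and array spread, the means of both lists over the 12 arrays had Pearson's r = -0.333 (permutation p = 0.295) and Spearman's rho = -0.559 (permutation p = 0.0626), and r = -0.491 without the 2 arrays farthest from the median, so the test could not decide. A lower Wnt response of the tumors in the deletion cannot be told apart from such admixture here.

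The leading axis of variation between arrays followed the spread of each array, with Pearson's r = 0.978 and Spearman's rho = 0.965 over 12 arrays (permutation p = 1e-05 and 2e-05, the first the smallest that the permutations can give) and r = 0.944 without the 2 arrays farthest from the median spread. Of 2 relations computed over arrays this one had Benjamini-Hochberg adjusted p = 2e-05 for r and 4e-05 for rho, and that of the Wnt and colonocyte lists 0.295 and 0.0626. A compression of all log2 values on some arrays may lie behind it. Across genes, which are not independent replicates, the loading on the axis rose with the mean level of the gene at a Spearman correlation of 0.465, below the 0.5 set in advance, so the test left this open. The 4 groups held a share of 0.464 of the variance of the axis (permutation p = 0.135), so tissue or genotype was not excluded either.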
